A study of Mus musculus with 19 samples.

How the data were processed

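The study profiled mouse skin squamous cell carcinoma with RNA-seq, ATAC-seq and Smad2/3 ChIP-seq, and 19 samples in 10 groups were described. Tumours grew as allografts from 10000 injected cells per the labels' protocols. Cells were sorted by CD71, the transferrin receptor encoded by Tfrc, and by retention of a histone H2B-GFP label that is diluted at each division. Quiescent cells were CD71 low and H2BGFP high, proliferative cells were CD71 high and H2BGFP low, and double negative cells were low for both. The RNA libraries came from 100000 sorted cells each, the ATAC libraries from 50000, and the ChIP and input samples from 12000000 cells, per the labels' protocols. The ChIP cells had been treated with 5 ng/mL TGFβ1 for 1 h in medium with 50 uM calcium, per the labels' protocols.

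For RNA, TopHat2 2.0.9, Cufflinks 2.2.0 and Cuffdiff 2.2.0 were used with build mm10, per the submitters' processing notes, which also name mm9 for the double negative libraries. The expression values are log2 ratios between sorted populations of the same tumour, as deposited by the authors, and their scaling between libraries is not given in the sources used here. The deposited table of log2 ratios holds 1609 genes, and the rule by which genes entered it is not given in the sources used here. It gives neither expression levels nor q-values, so the depth behind each ratio is unknown and no test of single genes was run. In the quiescent against proliferative columns 32 genes have a value at or within 0.1 of the table's limit of 12 in size, and a ratio at the limit is listed here as such and gives no fold. Bowtie and Picard 1.88 were used for the ChIP and input libraries and Bowtie for the ATAC libraries, with mm10, per the submitters' processing notes. The callers of peaks, motifs, copy number and mutations are not given in the sources used here. Smad2/3 sites and ATAC peaks were given as positions without a score, and the ATAC list merges the peaks of several libraries. For that reason populations, and the Tgfbr2 knockout libraries, were not compared in accessibility. The copy number table gives a whole number of copies per region, with a p-value per region computed by the authors, and calls it a gain or a loss. The mutation table gives the read count at each site as deposited by the authors, the percent of reads with the alternative base as a whole percent by the authors, and the authors' quality score, which was not used. It covers the proliferative and quiescent libraries of both tumours.

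Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. A gene was counted as higher or lower in a population when its log2 ratio had the same sign in SCC1 and SCC2, which takes the place of the planned rule on the authors' q. The samples of a group are the 2 tumours, so no spread within a tumour is known. The 24 gene lists, the groups, the tests and the rule for named genes were fixed before the data were examined. Each list with at least 5 members in the table was tested with a two-sided Fisher exact test of higher against lower members, set against the other genes of the table, with Benjamini-Hochberg adjustment over 16 lists at a threshold of 0.05. Genes of a list are regulated together and are not independent replicates, so these p-values describe the lists in these tumours. Agreement of direction was tested with an exact binomial test against 0.5.

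Gene coordinates came from a reference annotation of the GRCm38.p6 assembly, the assembly that mm10 names, and 1600 genes were matched, 1492 by symbol and 108 by a synonym. As a check of the build, 626 of 634 mutations lay inside the reference coordinates of their gene. The annotation gives no strand, so windows were the gene body with 10 kb either side. Overlaps of at least 1 bp were computed in Python in place of bedtools. Chance overlap came from 100 circular shifts within chromosomes with seed 1. Differences of medians and base change spectra were tested with two-sided permutation tests of 100000 resamples. Mutations were matched by position and alleles. Intervals are exact 95% binomial intervals. Those of allele shares were computed from the rounded percent and the depth and cover counting error only, since PCR copies are not independent molecules. The overlap of mutated genes was set against no chance value, because the table lists mutated genes only and gives no background of callable genes.

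The tests were tested on simulated data. For gene list direction, 100% of 200 simulated tables of 1600 genes with a list all higher passed the threshold, and 4.5% of those with a list at the overall rate did. For peaks per gene, a shift of 2 peaks was found in 100% of 50 simulated tables of 1300 genes, and no difference gave 0%, since a median of whole numbers is a coarse measure. For base change spectra the shares were 100% for another spectrum and 4% for the same one, in 200 simulated tables of 200 changes. The simulations drew genes of a list independently and peak counts without the long tail of the data. A difference of 1 peak, as in the data, was not simulated. These shares therefore check the code and do not give the power or error rate for the data.

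The named genes are, per direction, the 10 with the largest ratio among genes of the same sign in both tumours, and up to 4 members of each list with at least 3 members in the table. Tfrc, Tgfbr2, Cdkn1a and Smad7 were to be named whatever their values, and the last 3 have no row of their own in the table used here. For Smad2/3 sites the rule takes the 10 higher and 5 lower genes with the most sites, for copy number the 5 longest gains and losses per tumour and regions with a gene of the squamous carcinoma and Ras list, and for mutations the genes of that list and the 10 genes with the most mutations. The condition on expression level could not be applied, genes at the limit and the 5 entries that name several genes were left out of the ranking, and ranking by the mean of the tumours was chosen after the table was seen. A few items that the rule takes are not reported here. A few other genes are given as examples and were chosen after their values were seen. The basal epidermal, drug transport, iron, endothelial, melanocyte and muscle lists had 1 or 2 members in the table, and the red blood cell list had 0. Alternatives covered the size of the ratio, each tumour alone, the window, the overlap, gene length, read depth, matching and the strictness of copy number calls.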

Results

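RNA was compared between quiescent, proliferative and double negative cells sorted from 2 tumours, SCC1 and SCC2, with 1 library per population and tumour. ATAC-seq covered these populations and a double positive one in both tumours, with 2 further libraries from a Tgfbr2 knockout tumour, SCC3. Smad2/3 binding was mapped in SCC1 cells treated with TGFβ1, and input DNA of SCC1 and SCC2 served for copy number. The expression table holds 1609 genes with a log2 ratio per tumour for each pair of populations. No read totals are given with the ratios, so their depth is unknown, and there are no replicates within a tumour.

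The first comparison asked how label-retaining quiescent tumour cells differ in expression from fast-cycling ones. Compared with proliferative cells, quiescent cells had less RNA of the cell division machinery in both tumours. They had more RNA of TGF-β targets and of immediate early genes. Double negative cells differed from proliferative cells in the same directions, as given below. All 55 mitosis genes with a ratio, of 56 listed, were lower in quiescent cells of both tumours (Fisher exact test, adjusted p = 3.16e-12). Their median log2 ratio in the authors' deposited table was -4.38 in SCC1 and -1.71 in SCC2. All 39 DNA replication genes were lower as well, with medians of -2.38 and -1.30 in the authors' deposited table (Fisher exact test, adjusted p = 9.15e-09), as were all 24 DNA repair and checkpoint genes, with medians of -2.74 and -1.57 (Fisher exact test, adjusted p = 2.98e-05). Across the table, 576 genes were higher and 841 lower in quiescent cells of both tumours, and 192 had opposite signs or a ratio of 0.

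Tfrc, the CD71 surface protein used for sorting, had a log2 ratio of -1.72 in SCC1 and -1.55 in SCC2 in the authors' deposited table. The proliferation marker Mki67 stood at -5.90 and -2.28 in the authors' deposited table. Ndc80 and Nuf2, parts of the kinetochore complex that holds chromosomes to the spindle, had ratios of -5.74 and -6.38 in SCC1 and of -2.98 and -2.29 in SCC2 in the authors' deposited table. The mitotic phosphatase gene Cdc25c was at -6.52 and -1.58 in the authors' deposited table. Other genes with the lowest ratios in the authors' deposited table were the kinetochore genes Cenpm (-8.14 in SCC1, -1.54 in SCC2), Ska1 (-8.08, -0.73) and Casc5 (-5.81, -2.57), and the cohesin acetyltransferase Esco2 (-6.09, -3.43). The DNA glycosylase Neil3 (-6.60, -1.69), Ankle1 (-4.80, -4.25) and BC030867 (-4.90, -3.87) complete that group in the authors' deposited table. Among replication genes, the authors' deposited table gave Mcm10, needed to start replication forks, -4.68 and -2.20, Rrm2, a subunit of the enzyme that makes deoxynucleotides, -4.07 and -2.04, Uhrf1 -4.27 and -1.86, and E2f8 -3.69 and -1.98. Among repair genes it was Fancd2 of the Fanconi anaemia pathway (-6.59, -0.96), Clspn (-4.74, -1.20), Rad51ap1 (-4.69, -1.81) and Rad54b (-3.65, -2.32) in the authors' deposited table.

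Of 38 listed TGF-β target genes 10 had a ratio. Of these 10, 9 were higher in quiescent cells of both tumours and 0 lower (Fisher exact test, adjusted p = 0.000778). Their medians in the authors' deposited table were 1.55 in SCC1 and 1.50 in SCC2. The direction of the listed genes without a ratio is unknown. Ctgf, a secreted matricellular factor, had log2 ratios of 3.08 and 3.49, the TGF-β pseudoreceptor Bambi 1.13 and 2.82, fibronectin (Fn1) 1.89 and 1.66, and Ltbp4, which binds latent TGF-β, 1.73 and 1.60 in the authors' deposited table. The gene that differed in sign was Tnc, at -0.33 and 3.24 in the authors' deposited table. Some of these genes are also expressed by stromal cells, and in the authors' deposited table the fibroblast and immune lists had medians of 0.09 and -0.34 in SCC1 and of 4.28 and 2.95 in SCC2. In SCC1 alone, a test chosen after the data were seen, 9 TGF-β targets were higher and 1 lower (exact test, adjusted p = 0.00320). Of 36 listed genes of the TGF-β and BMP pathway 7 had a ratio, with 6 higher and 0 lower (Fisher exact test, adjusted p = 0.0102). With ratios of 1 or more in both tumours 2 were left, with an adjusted p of 0.213 in the exact test. With each tumour alone, also chosen after the data were seen, the pathway passed in SCC1 with 7 of 7 genes higher (exact test, adjusted p = 0.00320) and not in SCC2 with 6 of 7 (exact test, adjusted p = 0.0679). Id1 and Id3, inhibitors of basic helix-loop-helix factors, stood at 2.93 and 2.70 in SCC1 and at 1.90 and 2.14 in SCC2 in the authors' deposited table. The co-receptor Eng was at 0.72 in SCC1, and the ligand Tgfb1 at 1.44 in SCC1 and 0.08 in SCC2 in the authors' deposited table.

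Immediate early and heat shock genes were higher for 13 of 15 members and lower for 1, with medians in the authors' deposited table of 1.77 in SCC1 and 0.85 in SCC2 (Fisher exact test, adjusted p = 0.000268). Fosb (2.66 in SCC1, 1.16 in SCC2), Fos (2.26, 1.07) and Atf3 (2.01 in SCC2), which encode AP-1 and related transcription factors, and the phosphatase gene Dusp1 (1.77, 2.65) were the leading members in the authors' deposited table. Such genes also respond to cell dissociation as background knowledge, and the protocol of dissociation is not given in the sources used here.

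Fibroblast genes were higher for 9 of 13 members and lower for 0 (Fisher exact test, adjusted p = 0.000778), but their median log2 ratio in the authors' deposited table was 0.09 in SCC1 and 4.28 in SCC2. Collagen genes Col1a1 (0.05, 4.60) and Col3a1 (0.08, 4.63) were near 0 in SCC1 and high in SCC2, while the proteoglycan decorin, Dcn, stood at 2.75 and 2.54 in the authors' deposited table. Thy1 (0.62, 5.38), Loxl1 (0.28, 4.98) and Col6a2 (-0.43, 5.22) had the other leading ratios of the list in the authors' deposited table. The list no longer passed with ratios of 1 or more in both tumours, where 1 gene was left (exact test, adjusted p = 0.416), nor in SCC1 alone, where 9 of 13 genes were higher (exact test, adjusted p = 0.0803).

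Immune, interferon response, and stress and wound genes also had higher medians in quiescent than in proliferative cells of SCC2. Against double negative cells of SCC2 the interferon median was -0.014, while that of fibroblast genes was 3.11. Immune genes had medians of -0.34 in SCC1 and 2.95 in SCC2 in the authors' deposited table, with Tyrobp, a signalling adaptor of myeloid cells, at -0.30 and 4.24, H2-Eb1 at -0.13 and 3.27, Cd14 at 0.28 and 2.74 and H2-Ab1 at 1.65 and 2.49. Interferon response genes had medians of -0.67 and 2.01 in the authors' deposited table, with the chemokine gene Cxcl10 at -1.48 and 3.19, Usp18 at -0.16 and 2.12, Irf7 at -0.12 and 1.89 and Irf9 at 0.57 and 1.17. Of the immune genes 2 of 8 and of the interferon genes 1 of 16 were higher in both tumours (Fisher exact tests, adjusted p = 0.220 and 0.438). In tests of each tumour alone, chosen after the data were seen, interferon genes were higher for 16 of 16 in SCC2 (exact test, adjusted p = 1.11e-05) and lower for 15 of 16 in SCC1 (exact test, adjusted p = 0.0176), and immune genes were higher for 8 of 8 in SCC2 (exact test, adjusted p = 0.00341) and for 2 of 8 in SCC1 (exact test, adjusted p = 0.766). Stress and wound genes were higher for 2 of 5 members (Fisher exact test, adjusted p = 0.220), with Krt6b at -3.71 and 3.22, S100a8 at -0.23 and 4.53, S100a9 at 0.21 and 4.43 and Il1b at 0.16 and 4.07 in the authors' deposited table.

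The remaining tested lists did not pass the adjusted threshold. Their counts cover only listed genes with a ratio, such as 5 of 20 hair follicle stem cell genes and 5 of 54 keratinocyte differentiation genes. Hair follicle stem cell genes were higher for 4 of 5 members and lower for 0 (Fisher exact test, adjusted p = 0.0543), led in the authors' deposited table by the Wnt inhibitor Sfrp1 (2.64 in SCC1, 1.95 in SCC2) and the stem cell receptor Lgr6 (1.79, 0.91). Dkk3 stood at 0.89 and 0.60, and Postn, of opposite sign in the tumours, at 4.12 in SCC2 in the authors' deposited table. Ribosome biogenesis and MYC target genes were lower for 9 of 10 members (Fisher exact test, adjusted p = 0.0987), among them Mycn (-1.88, -1.51), Rrp12 (-1.16, -1.82), Dkc1 (-1.08, -1.02) and Nop58 (-1.09, -1.07) in the authors' deposited table. Cell cycle inhibitors were split, 5 higher and 2 lower of 9 (Fisher exact test, adjusted p = 0.204). The antiproliferative gene Btg2 stood at 2.03 and 1.25 and Gadd45g at 1.04 and 1.40, while the CDK inhibitor gene Cdkn2c was at -1.64 and -1.46 and Rbl1 at -1.30 and -1.21 in the authors' deposited table. Of 11 glutathione and NRF2 genes 3 were higher and 8 lower (Fisher exact test, adjusted p = 0.541). The glutathione peroxidase Gpx2 was at -3.07 in SCC1 and the quinone reductase Nqo1 at -1.39 and -1.22, while the extracellular enzymes Gpx3 (0.35, 4.53) and Sod3 (1.84, 4.10) were higher in the authors' deposited table. Keratinocyte differentiation genes were higher for 3 of 5 members and lower for 1 (Fisher exact test, adjusted p = 0.382), with Prdm1 at 1.20 and 1.02, Krt13 at -1.31 and -0.79 and Krtdap at -1.77 and 0.13 in the authors' deposited table. Of 6 squamous carcinoma and Ras genes 5 were lower and 1 higher (Fisher exact test, adjusted p = 0.438), with Brca1 at -3.88 and -1.95 and the cyclin gene Ccnd1 at -0.62 and -1.30 in the authors' deposited table.

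Outside these lists, genes with some of the largest ratios towards quiescent cells in the authors' deposited table were Cp, which encodes ceruloplasmin (2.89 in SCC1, 5.03 in SCC2), Fmo1 (2.45, 5.33) and C1qtnf3 (1.79, 6.22). The authors' deposited table also had Slitrk5 (1.95, 5.66), Tmprss11g (2.73, 4.86), the histone gene Hist1h4h (2.35, 5.19), Fam71a (3.21, 3.87), Odam (1.05, 6.05) and 2310005G13Rik (0.42, 7.77) in that group. Direction was the same in SCC1 and SCC2 for 1417 of 1604 genes with a nonzero ratio in both, or 88.3% (95% interval 86.7 to 89.9; exact binomial test, p = 6.67e-234). Across genes, which are not independent replicates, Pearson's r was 0.65 and Spearman's rho 0.71, with ratios at the limit included. Without genes at the limit Pearson's r was 0.59 over 1573 genes. Genes regulated together are not independent trials either, so the binomial p-value is too small. The table holds genes selected by the authors, so the share of 88.3% does not describe all expressed genes.

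**Figure D1:**
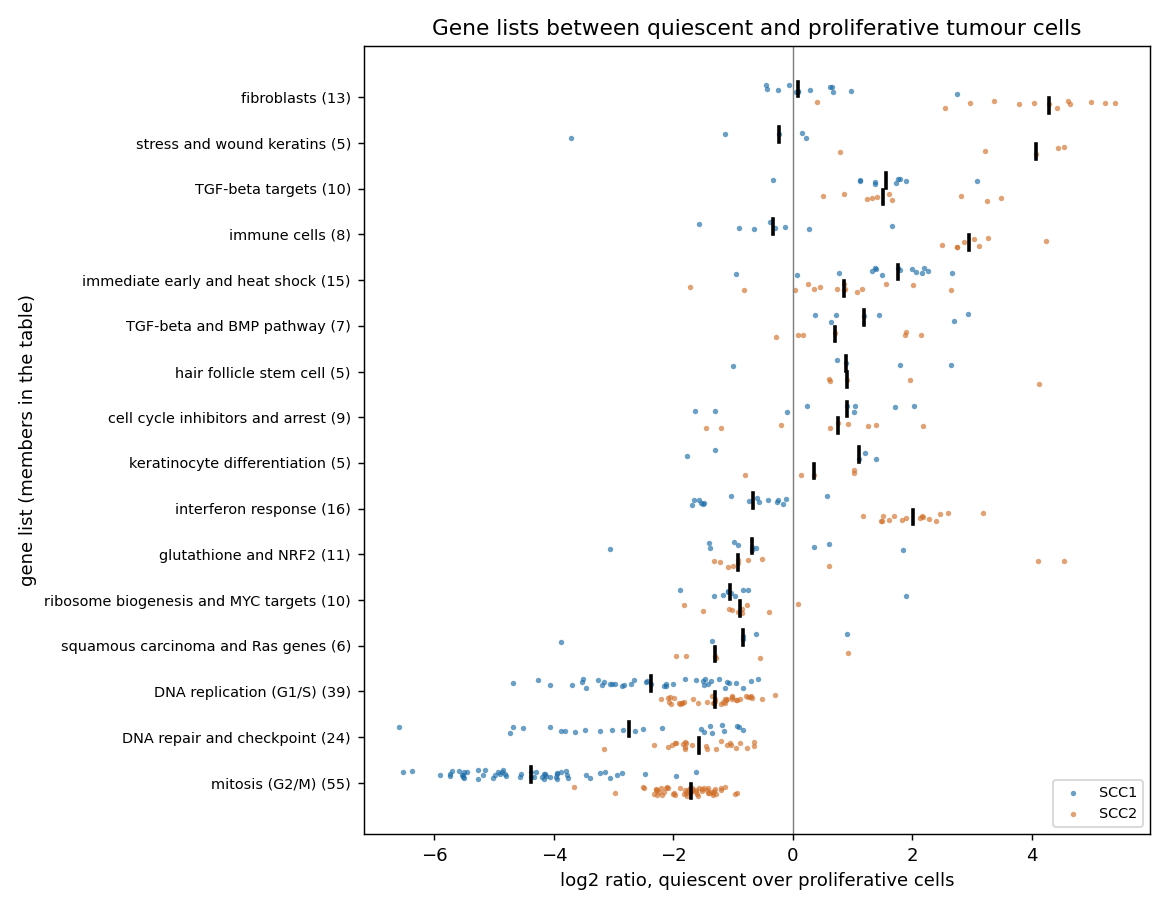
Each point is a gene of the authors' deposited table, placed by its log2 ratio of quiescent over proliferative cells on the x axis and by gene list on the y axis, in blue for SCC1 and orange for SCC2, with black bars at the list medians. The mitosis medians lie at -4.38 in SCC1 and -1.71 in SCC2, and the fibroblast medians at 0.09 and 4.28.

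Double negative cells, low for both the CD71 and the label signal, were compared with the other populations. Against proliferative cells they too had less RNA of division genes, with median log2 ratios for mitosis genes of -3.52 in SCC1 and -3.21 in SCC2 in the authors' deposited table, and all 55 genes lower in both tumours (Fisher exact test, adjusted p = 2.26e-14). All 39 replication genes (Fisher exact test, adjusted p = 5.24e-10) and all 24 repair genes (Fisher exact test, adjusted p = 2.94e-06) were lower. All 10 TGF-β targets with a ratio were higher in double negative than in proliferative cells (Fisher exact test, adjusted p = 0.00119). So were 6 of 7 pathway genes (Fisher exact test, adjusted p = 0.0157), 13 of 15 immediate early genes (Fisher exact test, adjusted p = 0.00351) and 5 of 5 hair follicle genes (Fisher exact test, adjusted p = 0.0311). Ribosome biogenesis genes were lower for 9 of 10 members (Fisher exact test, adjusted p = 0.0113). Fibroblast genes were higher for 11 of 13 members (Fisher exact test, adjusted p = 0.00067), with medians of 2.67 in SCC1 and 1.24 in SCC2 in the authors' deposited table, and immune genes for 6 of 8 (Fisher exact test, adjusted p = 0.0157). In all, 685 genes were higher and 819 lower in double negative than in proliferative cells of both tumours, and the direction was shared by 1504 of 1601 genes, or 93.9%. This share too covers only genes selected by the authors. The submitters' processing notes also name mm9 for the double negative libraries, and whether this affects ratios that use them was not tested.

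Between quiescent and double negative cells the tumours did not share a direction. Only 746 of 1605 genes, or 46.5%, had the same sign, with 263 higher and 483 lower in quiescent cells of both tumours, and no list passed the adjusted threshold. Each tumour alone, a setting chosen after the data were seen, gave 467 higher and 1141 lower in SCC1 and 919 higher and 687 lower in SCC2. Of genes with ratios of 1 or more in both tumours, 58 of 196, or 29.6%, had the same sign (exact binomial test, p = 1.06e-08), so most of these had opposite signs. At this size the same sign was found for 94.2% of 591 genes between quiescent and proliferative cells and for 98.5% of 666 between double negative and proliferative cells. Genes regulated together are not independent trials, and each population has 1 library per tumour, so the binomial p-value is too small. Mitosis genes had a median of -1.06 in SCC1 and 1.34 in SCC2, and fibroblast genes of -2.69 and 3.11, in the authors' deposited table. TGF-β targets had medians of 0.06 and -0.13, and immediate early and heat shock genes of 0.57 and -0.49, in the authors' deposited table. Of the 10 TGF-β targets 1 was higher and 2 were lower in quiescent than in double negative cells of both tumours. These comparisons share libraries with the first one, so their lists are not independent of it.

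**Figure D2:**
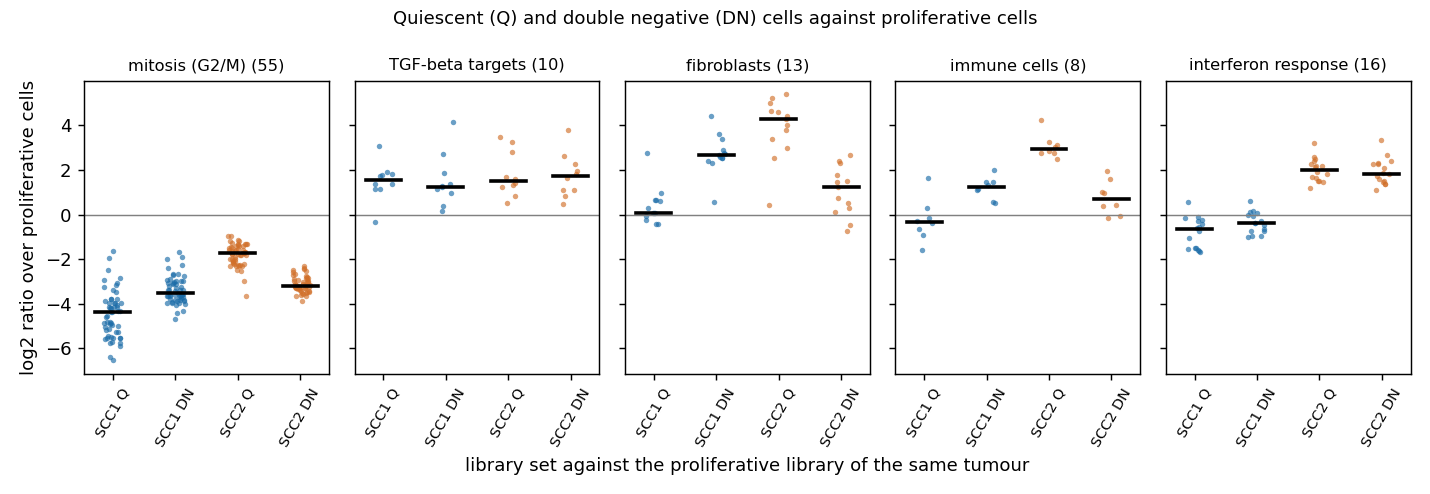
Points are genes of the authors' deposited table in 5 lists, with log2 ratio over the proliferative library of the same tumour on the y axis and the quiescent (Q) and double negative (DN) libraries of SCC1 (blue) and SCC2 (orange) on the x axis, and bars are medians. The fibroblast median is 0.09 in SCC1 Q, 2.67 in SCC1 DN, 4.28 in SCC2 Q and 1.24 in SCC2 DN.

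Smad2 and Smad3 carry the TGF-β signal to DNA, and their sites in treated SCC1 cells were set against accessible regions and genes. The list holds 6143 sites of 201 bp, from 1 ChIP sample, and by its name only bound sites with a motif, so binding without a motif is not counted and a site here means a listed one. Of these, 3690 lay in a merged ATAC peak, or 60.1% (exact 95% interval 58.8 to 61.3), against a mean of 1.94% (range 1.43 to 2.38) in 100 circular shifts. A site lay within 10 kb of 152 of 575 genes higher in quiescent cells, or 26.4% (22.9 to 30.2), and of 157 of 836 lower genes, or 18.8% (16.2 to 21.6), with an odds ratio of 1.55 (two-sided Fisher exact test, p = 0.000818). With ratios of 1 or more in both tumours the odds ratio was 1.50 (Fisher exact test, p = 0.0759). Adjusted for log2 gene length and number of ATAC peaks in a planned logistic model, it was 1.36 (model interval 1.03 to 1.80). Other protein-coding genes had a site in 14.9% of 20370 cases. Of ATAC peaks in SCC1 gains 7.09% (6.73 to 7.47) held a site, against 5.87% (5.64 to 6.10) of peaks without a call. Higher genes lay in SCC1 gains more often than lower genes, 51.0% against 40.8%. None of these odds ratios was adjusted for copy number.

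Of the higher TGF-β targets, 4 of 9 had a site, and of the pathway genes 4 of 6, against 26.4% of all higher genes. Single lists were not tested for sites, and the counts are small. Other lists had shares of similar size, such as 5 of 8 glutathione and NRF2 genes lower in quiescent cells. The counts therefore do not show that sites favoured TGF-β genes. Id1 (mm10 chromosome 2, 152736251 to 152737410) had 5 sites, 1 of them inside the gene at 152736313 to 152736513 and in an ATAC peak. The site of Ctgf lay in the gene body on chromosome 10 at 24596411 to 24596611, outside peaks. The co-receptor gene Eng (chromosome 2, 32646595 to 32682669) had 4 sites and Tgfb1 3. The most sites near a higher gene, 15, were at the sorting receptor gene Sorcs2 (chromosome 5, 36017180 to 36398197), followed by the cadherin gene Cdh13 with 8, 2010111I01Rik and the taurine transporter gene Slc6a6 with 6 each, and Auts2 and R74862 with 5 each. Cyp26b1, which breaks down retinoic acid, and 2610307P16Rik had 4 each. Among lower genes, the growth factor gene Nrg1 had 7 sites, Celsr1, Tbcd and Actn1 had 6 each, and Fbln1 had 4. These counts cover the gene body and were not adjusted for gene length, so longer genes can hold more sites.

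The merged ATAC list held 61553 peaks with a median width of 550 bp (quartiles 450 to 650), covering 35.6 Mb. Over protein-coding gene bodies lay 57.3% of peaks (56.9 to 57.7). Peaks within 10 kb had a median of 3 per higher gene and 2 per lower gene (two-sided permutation test, p = 0.453). Per 10 kb of window the medians were 0.739 and 0.476 (permutation test, p = 1e-05, the smallest these resamples can give), and higher genes were shorter, with a median length of 11.3 kb against 26.7 kb. Among these higher and lower genes, most peaks were found at the phosphodiesterase gene Pde4d with 52, Nrg1 with 44, 2010111I01Rik with 41 and Cdh13 with 27. These counts were not adjusted for gene length either.

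Copy number from the input DNA was compared between the tumours, with 1 input library each and so no test between them. The authors called 137 gains over 745 Mb and 14 losses over 92.2 Mb in SCC1, and 125 gains over 704 Mb and 18 losses over 77.9 Mb in SCC2. Gains shared 514 Mb, against a mean of 302 Mb (range 253 to 367) in 100 circular shifts. The shifts do not keep gene density, and gains of both tumours held more protein-coding genes per Mb than regions without a call. The excess therefore does not by itself separate shared tumour gains from a feature common to both input libraries. Losses shared 24.0 Mb, which 25 of 100 shifts reached. The long gains were chromosome 10 from 1 to 62300000 at 3 copies in both tumours, chromosome 4 from 1 to 44400000 in SCC1, chromosome 10 from 63500001 to 126800000 in SCC2, and chromosome 7 from 1 to 35700000 in SCC2. Further long gains were at chromosome 17 from 15500001 to 43200000, chromosome 15 from 37300001 to 63200000 with Myc, and chromosome 11 from 1 to 24000000 with Egfr in SCC1, and at chromosome 11 from 1 to 31600000 with Egfr in SCC2. The longest loss covered chromosome 14 from 58000001 to 118100000 in SCC1, at 1 copy, with the retinoblastoma gene Rb1, and 0% of it was called lost in SCC2. SCC2 had losses at chromosome 14 from 21100001 to 39500000 and from 1 to 12800000, at chromosome 4 from 109500001 to 116000000 and at chromosome 8 from 88300001 to 94000000. A loss on chromosome 1 from 185400001 to 190900000 in SCC1 was called lost over 94.5% of its length in SCC2.

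Of 60 genes of the squamous carcinoma and Ras list, 28 lay in gains in SCC1 and 25 in SCC2, with 23 in both. The share of all genes in gains was not set beside these counts. Gains held 12.5 protein-coding genes per Mb in SCC1 and 12.6 in SCC2, against 6.48 and 6.47 in regions without a call. The counts therefore do not show that gains favoured the listed genes. Hras had 4 copies in SCC1 and no call in SCC2, Trp53 and Egfr had 4 copies in SCC1 and 3 in SCC2, and Myc had 3 in both. Rb1 was lost in SCC1 and Trp73 in SCC2. Genes higher in quiescent cells lay in gains more often than lower genes, 51.0% against 40.8% in SCC1 (Fisher exact test, adjusted p = 0.000686). In SCC2 it was 49.2% against 40.6% (Fisher exact test, adjusted p = 0.0026). Genes of the same gained region share its call and are not independent, and no shifted regions were used here, so these p-values are too small. Both populations come from the same tumour, so the difference is not read as an effect of copy number. With ratios of 1 or more in both tumours the odds ratios were 1.32 and 1.21 (Fisher exact tests, p = 0.145 and 0.317). Losses held 1.74% of higher and 1.44% of lower genes in SCC1, and 1.57% and 1.32% in SCC2 (Fisher exact tests, adjusted p = 0.819 in both).

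**Figure D3:**
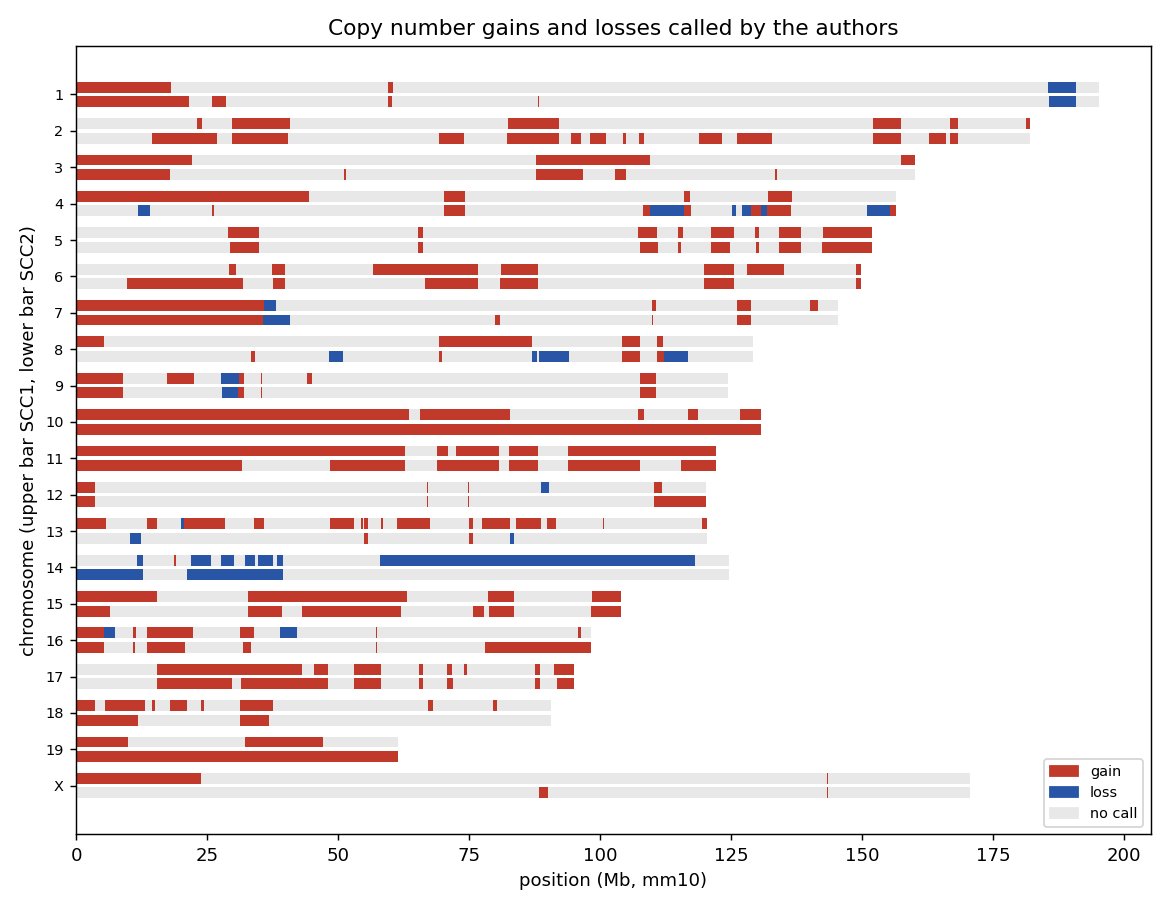
Gains (red), losses (blue) and regions without a call (grey) are drawn by position in Mb on the x axis for each chromosome on the y axis, with SCC1 as the upper and SCC2 as the lower bar. The loss of chromosome 14 from 58000001 to 118100000 appears in SCC1 alone, and the gain of chromosome 10 from 1 to 62300000 in both.

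Nonsynonymous mutations called from RNA were compared between tumours, and such calls need expressed genes and enough reads. The table lists 656 mutations, 564 in SCC1 and 436 in SCC2, and 344 in both, or 52.4% (exact 95% interval 48.5 to 56.3). By library, 498 were listed in SCC1 proliferative, 422 in SCC1 quiescent, 411 in SCC2 proliferative and 95 in SCC2 quiescent cells, with median depths of 35, 40, 33 and 19 reads. The 2 libraries of SCC1 shared 84.4% of the smaller list, and those of SCC2 73.7%. Between the tumours the proliferative libraries shared 79.1% and the quiescent ones 75.8%. A change listed in 1 tumour alone may thus be present but unlisted in the other. The mutated genes numbered 468 in SCC1 and 376 in SCC2, with 304 in both.

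The Ras gene Hras carried Q61L (mm10 chromosome 7, position 141192550, exon 3, coding change A182T, counted from the start of the coding sequence) in all 4 libraries. The share of reads with it was 62% (57.9 to 66.1, 561 reads) in SCC1 proliferative, 67% (61.8 to 71.8, 360 reads) in SCC1 quiescent, 57% (52.1 to 61.9, 405 reads) in SCC2 proliferative and 62% (47.0 to 74.7, 52 reads) in SCC2 quiescent cells. The tumour suppressor gene Trp53 carried R277S (chromosome 11, position 69589630, exon 8) in all 4 libraries at 63%, 68%, 62% and 69%, and N128Y (position 69588379, exon 5) in 3 libraries at 32% and 29% in SCC1 and 41% in SCC2. The acetyltransferase gene Crebbp with T2430S and the kinase gene Ripk4 with S739C were listed in both tumours. Myc D87E, Keap1 H96L, Ep300 A2252D and Syne2 E344D were listed in SCC1 alone, and Ep300 R1341W in SCC2 alone, at depths from 15 to 51 reads. The genes with the most mutations were the histocompatibility genes H2-Q4 with 10, H2-K1 with 7 and the joint entry of H2-D1 and H2-L with 7, and Erdr1 with 8. Gm8909 followed with 6, Serpina3i with 5, and Gstp2, H2-Q2, Ifi202b, Krt42 and Txndc17 with 4 each. Many of these belong to families of near-identical copies, so their calls are uncertain.

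Base changes from A:T to T:A made up 46.8% of 331 shared single-base changes, 29.3% of 188 listed in SCC1 alone and 28.8% of 66 listed in SCC2 alone. The spectra of the changes private to each tumour did not differ detectably (chi-square 1.39; two-sided permutation test, p = 0.928). Shared and private spectra differed (chi-square 22.1; permutation test, p = 0.00056), a comparison chosen after the data were seen.

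**Figure D4:**
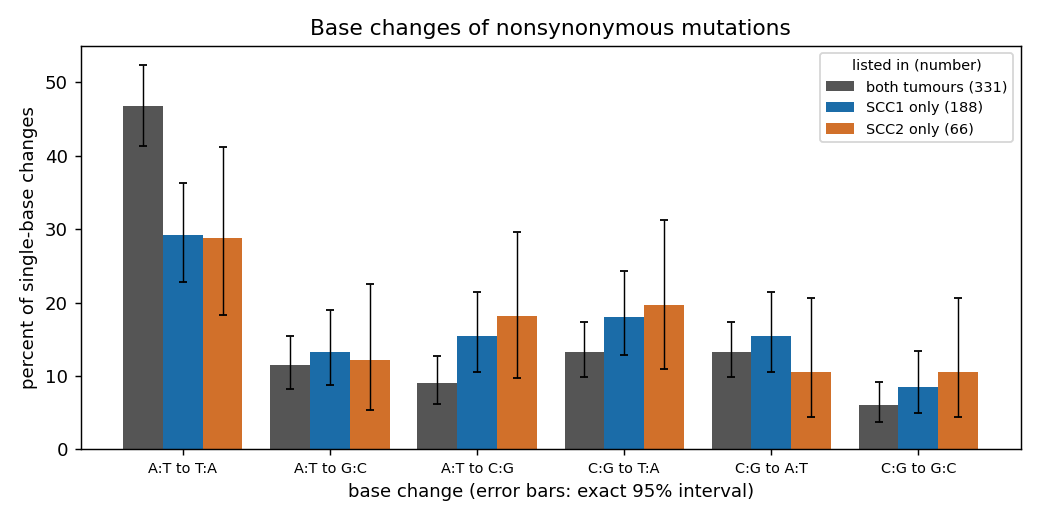
Bars give the percent of single-base changes in each of 6 base change classes on the x axis, for changes listed in both tumours (grey, 331), SCC1 only (blue, 188) and SCC2 only (orange, 66), with exact 95% intervals. The A:T to T:A bar stands at 46.8% for shared changes and at 29.3% and 28.8% for the private ones.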

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

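All tests of explanations given here were chosen after the results were seen, except that of a common origin of the tumours by allele shares, which was written before these were compared. The gene list results that follow were singled out because these lists moved in opposite ways in SCC1 and SCC2. The shared mutations, given last, were taken up apart from this rule. Differences between the tumours are SCC2 minus SCC1 medians of log2 ratios in the authors' deposited table, and were not tested. Between quiescent and proliferative cells the difference was 4.30 for stress and wound genes, 2.68 for interferon response genes and 3.29 for immune genes. Between quiescent and double negative cells it was 5.80 for fibroblast genes, 5.92 for stress and wound genes, 3.88 for immune genes, 2.41 for mitosis genes, 1.02 for DNA replication genes and -1.06 for immediate early genes. Between double negative and proliferative cells it was 2.19 for interferon response genes.

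Fibroblast and immune genes were high in the SCC2 quiescent and SCC1 double negative libraries. A candidate explanation is carry-over of stromal cells in the sort, although the H2BGFP gate on quiescent cells would select against unlabelled host cells, and other gates are not given in the sources used here. The immune list median of 2.95 in SCC2 quiescent cells is what carry-over needs, but this list is part of the pattern, so the value could hardly have come out otherwise and carry-over stays open, and 4 of its 8 members are class II genes or Cd74, which interferon can also raise. The host share of the SCC2 quiescent library stays open as well, since the median ratio of allele shares of 1.05 between quiescent and proliferative cells (95% bootstrap interval 0.966 to 1.14, n = 54) rests on mutations listed in both libraries, while 95 were listed in quiescent and 411 in proliferative cells and those with a lowered share could have dropped out. A mesenchymal shift of the tumour cells would not bring immune RNA, so as the whole account it is argued against by the 8 of 8 immune genes with a ratio above 1, 4 of them outside class II and Cd74, but for the fibroblast genes, with a median of 4.28, it stays open, as does a difference between the tumours.

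Interferon response genes were high in SCC2 and not in SCC1. Within SCC2 the interferon median between quiescent and double negative cells was -0.014, with a highest member of 0.75, against 3.11 for fibroblast and 2.30 for immune genes. These values argue against carry-over in proportion to the fibroblast and immune genes. The comparison and its prediction were written from values already seen, and rest on 1 library per population, so they are no independent test. Carry-over of other stromal cells stays open, since the interferon median of -0.36 in SCC1 double negative cells, beside a fibroblast median of 2.67, comes from 1 library of the other tumour. A response of the quiescent population alone is argued against by the same median of -0.014. Both other SCC2 libraries stood above the proliferative one, with 1.83 for double negative cells, so a low SCC2 proliferative library and a difference between the tumours cannot be told apart with 1 library per population.

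SCC1 and SCC2, described as independent tumours, shared 344 mutations. Strain variants as the whole account are argued against by the A:T to T:A share of 51.6% among shared changes outside chromosomes 17 and Y (45.6 to 57.5, n = 289), and 1 culture under 2 names by the loss on chromosome 14 in SCC1, of which 0% was called lost in SCC2. A common origin of the tumours may account for them, since shared changes had higher median allele shares than private ones in the proliferative libraries, by 7.5 percentage points in SCC1 (permutation test, p = 0.0078) and 15 in SCC2 (permutation test, p = 0.0002). Changes with a high allele share are also more readily listed in both tumours, so this difference does not by itself separate the explanations. Of the breakpoints of SCC1 copy number regions of 1 Mb or more, 75 of 180 lay within 100 kb of an SCC2 breakpoint, against a mean of 2.16 and a highest value of 6 in shifted positions, as a common origin needs, but strain differences and regions that map poorly could give the same, which is untested without matched normal DNA.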

How the results depend on the processing

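Chosen after seeing the data were each tumour alone for lists, double negative cells, sites and peaks, direction in the same tumour for copy number, ratios of 1 or more for double negative cells, proliferative libraries alone for mutations, and the omission of genes at the limit, of genes with the stromal profile and of chromosomes 17 and Y. Of 118 alternative values, 89 counted as kept, meaning the same direction and side of the threshold, a count within 1.5 times the main one, or a share without a test inside the 95% interval of the main one; 7 lost their threshold, 6 passed it newly, 11 moved and 5 reversed. The direction of a list is that of its odds against the other genes, so stress and wound genes at 40% in SCC1 alone counted as kept, as did a difference of 0 peaks over gene bodies. With log2 ratios of 1 or more in both tumours 182 genes were higher and 375 lower in quiescent than in proliferative cells, 21 and 37 in quiescent than in double negative cells, and 250 and 406 in double negative than in proliferative cells, as fewer genes were counted. At this size the percent of higher members was 100% for the TGF-β and BMP pathway (2 genes) and for fibroblasts (1 gene), both no longer past the threshold, and 33.3% for glutathione and NRF2 genes, whose odds turned. The odds ratio was 1.50 for Smad2/3 sites, 1.32 and 1.21 for gains in SCC1 and SCC2, and 0.872 and 0.507 for losses, which turned. With each tumour alone the percent of higher members ranged from 85.7% to 100% for the pathway, 69.2% to 100% for fibroblasts, 40% to 100% for stress and wound genes, 80% to 100% for hair follicle genes, 6.25% to 100% for interferon genes and 25% to 100% for immune genes. SCC1 alone gave the low value in these lists except the pathway, where SCC2 alone did. Ribosome biogenesis genes stood at 10% in each tumour. In SCC2 alone the pathway missed the threshold (exact test, adjusted p = 0.0679), and stress and wound (0.0300), hair follicle (0.0300), ribosome (0.0390), interferon (1.11e-05) and immune genes (0.00341) newly passed it. Against double negative cells 467 genes were higher and 1141 lower in quiescent cells of SCC1 alone, and 919 and 687 in SCC2 alone. The share of Smad2/3 sites in peaks was 57.4% with at least 50% of the site covered and 67.5% within 1 kb, and the difference in peaks per 10 kb was 0.263, past the threshold. Where no construction shows it, the cause was not tested. No paired analysis was possible because there are no values per library to fit with and without the tumour, beyond the ratios themselves, which are differences within a tumour and whose signs were counted. A test of the 2 ratios of each gene was left out, as the genes are a selection. Alternatives that need expression levels, a pseudocount, adjusted p-values at 0.01, an estimated correlation, a site score, strand or database identifiers were not run, nor was the chance overlap of mutated genes. SCC2 quiescent cells had the fewest listed mutations and the lowest median depth, and whether depth is the cause was not tested. The depth of the ratios is unknown.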

Other observations

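The observations here were made after the data were seen. No explanation is offered for them, apart from the endothelial genes, which were set beside carry-over above. The 2 endothelial genes in the table, of 13 listed and not tested, were higher in double negative than in proliferative cells, with log2 ratios of 6.84 in SCC1 and 4.53 in SCC2 for the tight junction gene Cldn5 and of 3.34 and 1.63 for Egfl7 in the authors' deposited table. In quiescent over proliferative cells they stood at -0.83 and -0.61 in SCC1 and at 2.75 and 0.88 in SCC2 in the authors' deposited table. The hypoxia and glycolysis genes in the table, Ndrg1 (1.35 in SCC1, 0.71 in SCC2), Ankrd37 (1.37, 0.72) and the glucose transporter gene Slc2a1 (1.90, 0.09), were 3 of 3 higher in quiescent cells in the authors' deposited table. The epithelial-mesenchymal transition genes were mixed, with the adhesion gene Epcam at -3.21 and -0.40, the repressor gene Snai1 at -0.23 and 3.24, Mmp2 at 0.19 and 3.00 and Mmp10 at 0.57 and 2.43 in the authors' deposited table. Members of the short lists were Col7a1 (0.23, 2.56) and Itga2 (-2.19, -0.30) for basal adhesion, Aldh3a1 (-1.22, -0.77) and Ugt1a7c (0.88, 0.31) for drug metabolism, and Tnnt3 (-1.63, -0.27) for muscle in the authors' deposited table.

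In SCC1, the region of chromosome 10 from 116800001 to 118600000, which holds the p53 inhibitor gene Mdm2, was called at 11 copies. The region of chromosome 9 from 35300001 to 35400000 was called at 98 copies in SCC1 and 115 in SCC2. The authors' p-values for it were 0.0833 (Wilcoxon rank sum test) and 0.270 (Kolmogorov-Smirnov test) in both tumours. This call therefore fails the stricter cut of 0.01 on the Wilcoxon p. Gained regions held 12.5 protein-coding genes per Mb in SCC1 and 12.6 in SCC2, and regions without a call 6.48 and 6.47, with no matched normal DNA used here. Smad2/3 sites numbered 2.01 per 100 ATAC peaks on chromosome 14 and 1.66 on the X chromosome, against 16.6 on chromosome 18. On chromosome 14, 1.35% of peaks in SCC1 losses (0.787 to 2.15) and 1.70% of peaks without a call (1.03 to 2.64) held a site. Mutations in H2 genes, 49 in 15 genes, had a median allele share of 85%, against 44% for mutations outside chromosomes 17 and Y.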
